A study of Mus musculus with 5 samples.

How the data were processed

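ATAC-seq libraries of sorted GMPs from Ldlr-/- mice in the PBS arm were studied, with 2 CD, 2 WD and 1 WD>CD sample. Groups were taken from the labels, and replicate numbers follow the order of the records and pair no samples. The submitters' processing notes name Bowtie 1.1.1, Picard 1.134, MACS2 2.1.0.20140616, bedtools, DESeq2 1.14.1 and ChIPseeker 1.10.3, and the builds mm10 and mm9, without saying what each was used for. How reads were shifted for the transposase, filtered or merged into regions is not given in the sources used here.

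The deposited values were whole-number counts per region, 1 column per library, over 1 common set of 53024 regions of 135 to 4760 bases (median 467). The deposited table is named as normalized, but its counts had totals of 1127285 to 4135499 and medians of 11 to 46 per region, so they were treated as raw counts. The table has 10 columns of values. Columns were matched to samples by the sample titles: 4 matched, for CD and WD, and 6 matched no sample and were not used. WD>CD was therefore not analysed here, nor were its planned comparisons.

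Before the data were examined, limma on log2 normalized values had been chosen as the test, with edgeR's quasi-likelihood test in its place should the values be raw counts. The latter was used (edgeR 4.0.16, R 4.3.3): TMM factors (0.9556 to 1.039), 1 fit of the 4 libraries with diet as the only term, glmQLFit and glmQLFTest, two-sided, Benjamini-Hochberg adjustment over all regions, threshold 0.05, no filter. The fit had 2 residual degrees of freedom per region and 315.6 prior degrees of freedom, so the error of a region comes almost wholly from the trend over all regions. The median SE of a log2 fold change was 0.359. CPM are counts scaled by the TMM-adjusted library size. At the depths of these libraries 3 counts equal 0.698 to 2.79 CPM. The 95% intervals of count ratios are exact and cover counting error only.

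Coordinates are those of the table. A total of 9089 regions overlapped an end of a protein-coding gene of GRCm38 (mm10), against 856 and 864 after shifts of 20000 bases either way, so that build was used. The gene table (21900 protein-coding genes) holds neither strand nor exons. A region was called gene end when within 1000 bases of either end of a gene, gene body when otherwise inside one, and intergenic elsewhere, and took the name of the gene it overlapped or of the nearest. Start and stop sites could not be told apart, nor exons, introns and UTRs.

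Named regions followed a rule set before the data were examined: the 10 largest rises and falls past the threshold with the groups apart, 1 region per gene, filled with the smallest p where fewer passed. The rule also took up to 3 regions per list with the largest moderated t, of which examples are given, and always Nlrp3, Il1b, Irf8, Csf1r, Elane and Mpo. The 17 lists, fixed at the same time, held 571 genes, of which 567 matched. Lists and region classes were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and fry as alternatives. Camera compares a list with the other regions. The alternatives therefore give the list's median minus that of the background regions. This measure replaced the plain median after both had been seen. Of 306 list values under alternatives, 35 had the opposite sign to the main value with it and 41 with the plain median. The motif families were not tested, as no genome sequence was used here.

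In simulated counts for WD against CD over 53024 regions with 200 changed, 4.78% of changed regions were called at 1.5-fold, 24.2% at 2-fold and 80.6% at 4-fold (5 simulations). At an unadjusted p under 0.05 stood 4.83% of unchanged regions, and a mean of 3.8 unchanged regions per simulation were called at the adjusted threshold, beside the changed ones. A list of 86 regions shifted by 0.3 on the log2 scale had a camera p under 0.05 in 5 of 5 simulations, and an unshifted list in 0. The regions were simulated as independent of each other. These counts therefore do not cover lists whose regions vary together, such as the granulocyte list, with an estimated correlation of 0.217.

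Alternatives were a filter on low regions, quantile normalization, each library left out, DESeq2 1.42.0, a threshold of 0.1, and gene-end regions alone for lists. Added after seeing the data were RLE and library-total scaling, loess offsets for the regions and lists, limma with trend on log2(CPM + 1) and with 0.5 and 5 in place of 1, removal of the 4 mitochondrial regions, counts thinned to 1127285 per library, 1 test per gene, and lists by the nearest gene end.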

Results

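Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in granulocyte-monocyte progenitors (GMPs) sorted from Ldlr-/- mice. These mice lack the LDL receptor and develop high blood cholesterol on a fat-rich diet. The mice had received an intravenous injection of PBS, the vehicle control, 6 h before sacrifice. The series has 5 samples in 3 diet groups: CD (the chow diet of the study), WD (Western diet) and WD>CD (Western diet followed by a return to CD). The comparison of WD with CD, with 2 libraries each, asks whether a Western diet leaves GMP chromatin in a different state. The single WD>CD sample was not analysed here. The table held whole-number counts for 53024 regions, with totals of 1913524 and 4135499 in the CD libraries and 1127285 and 2005040 in the WD libraries. Median counts per region were 21 and 46 in CD and 11 and 20 in WD. Nothing in the labels says whether the 2 libraries of a group came from separate mice, so the spread between them may be technical. The p-values of single regions rest almost wholly on the trend of that spread over all regions. Camera p-values at the preset correlation of 0.01 measure a list against the spread across regions. Intervals of ratios of counts cover counting error only, and not the choice of these regions by p from the same counts.

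In WD, accessibility at 3 nuclear regions fell. These and 2 mitochondrial regions, whose raw counts did not follow library depth, were the 5 of 53024 regions past an adjusted p of 0.05 in edgeR's quasi-likelihood test. A region in the body of Adk, which encodes adenosine kinase (GRCm38 chromosome 14, 21433427 to 21433758), went from 12.3 ± 2.26 CPM (counts scaled to a common library size; SD, n = 2) in CD to 1.97 ± 1.48 in WD. Its log2 fold change was -2.36 (SE 0.50), with an edgeR adjusted p of 0.0408. In WD the region held 1 and 6 counts, against 27 and 46 in CD. A region in the body of Epg5, a tethering factor that brings autophagosomes to lysosomes (chromosome 18, 78001870 to 78002737), went from 35.2 ± 0.439 to 14.02 ± 7.74 CPM (SD, n = 2). Its log2 fold change was -1.47 (SE 0.28), with an edgeR adjusted p of 0.00874. The third region lay 13362 bases from Mark3, which encodes a kinase acting on microtubule-associated proteins (chromosome 12, 111560719 to 111561142). It held 29.3 ± 5.89 CPM in CD and 9.96 ± 2.27 in WD (SD, n = 2), a log2 fold change of -1.45 (SE 0.30) with an edgeR adjusted p of 0.0372. No nuclear region passed as higher in WD. The calls at Adk and Mark3 were lost whichever of the 4 libraries was left out (adjusted p 0.112 to 0.732 and 0.112 to 1), with log2 fold changes of -3.59 to -1.96 and -1.74 to -1.28. The call at Epg5 held only without WD replicate 1, with log2 fold changes of -2.04 to -0.84 over the 4 libraries left out.

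The 2 regions called higher in WD relative to library size lay on the mitochondrial genome at positions 5407 to 6407 and 15992 to 16250, and were picked out after their values were seen. Their log2 fold changes were 0.89 and 0.95, with edgeR adjusted p of 0.0246 and 0.0079. Their raw counts were nearly equal in all 4 libraries, at 1515, 1520, 1491 and 1415 for the first region in CD replicates 1 and 2 and WD replicates 1 and 2, while the library totals differed by up to 3.67-fold. In CPM the diets overlapped at both regions, with CD replicate 1 above WD replicate 2. At an unadjusted p under 0.05 stood 4487 regions, 2070 higher and 2417 lower in WD, where 2651 are expected by chance. Pearson's r of log2 CPM over all regions, which are not independent replicates, did not follow diet. It was 0.948 between CD replicate 2 and WD replicate 2, 0.943 between the CD libraries and 0.895 between the WD libraries. The highest values involved CD replicate 2, the library with the most counts. It was 0.907 between CD replicate 1 and WD replicate 2, and 0.903 between CD replicate 2 and WD replicate 1. Counting noise lowers r where counts are few, but CD replicate 1 and WD replicate 2 had similar totals (1913524 and 2005040). CD replicate 2 was no closer to CD replicate 1 (0.943) than to WD replicate 2 (0.948). WD replicate 1 was closer to WD replicate 2 (0.895) than to CD replicate 1 (0.855). These comparisons differ, so r does not decide whether the libraries group by diet. DESeq2 called 0 regions, with 651 at an unadjusted p under 0.05, and 0 regions passed without CD replicate 2. Without the mitochondrial regions 1 call was left, at Epg5, while Adk and Mark3 kept log2 fold changes of -2.36 and -1.45 (edgeR adjusted p = 0.0589 each).

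**Figure D1:**
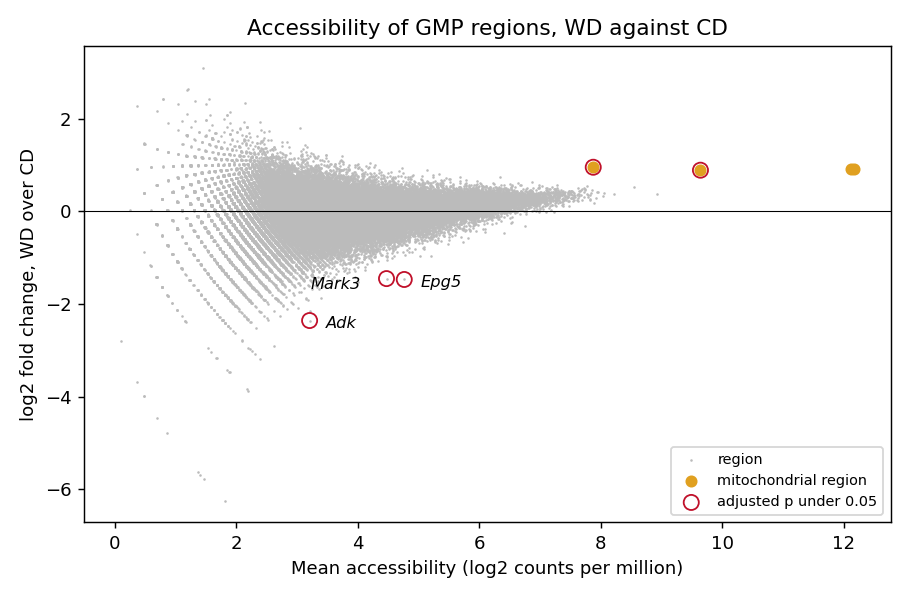
Log2 fold change of each of the 53024 regions, WD over CD, against its mean accessibility in log2 CPM. Open circles mark the 5 regions past an adjusted p of 0.05: the falls at Adk, Epg5 and Mark3 and 2 of the 4 mitochondrial regions (filled).

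Among regions with a named gene and both WD libraries below both CD libraries, the 7 with the next smallest p did not pass, with edgeR adjusted p of 0.0819 to 0.121. They lay in the bodies of Efcab14, Tmem260, Myo1e and Slc24a4, in Kdm4d and Gcat within 1000 bases of a gene end, and 14165 bases from Hdac4. Efcab14 held 12.3 ± 2.95 CPM in CD and 2.65 ± 0.191 in WD (SD, n = 2), and Tmem260 held 19.1 ± 5.20 and 7.41 ± 2.65. Gcat, an enzyme of threonine breakdown, held 12.8 ± 2.03 and 3.19 ± 1.89 CPM. The WD libraries together held 3 counts at Kdm4d, a histone demethylase gene, against 47 in CD, a WD over CD ratio of 0.13 (95% interval 0.026 to 0.404). They held 1 count at Myo1e, a class I myosin gene, and 1 at Hdac4, a histone deacetylase gene, each against 34 in CD (ratio 0.06, 0.001 to 0.357). Slc24a4 had 2 counts in WD and 40 in CD (ratio 0.102, 0.012 to 0.393). These regions were picked by p from the same counts, so the ratios may be too extreme and the intervals are no further support.

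Rises were taken among regions with a named gene and both WD libraries above both CD libraries. The 10 with the smallest p had edgeR adjusted p of 0.121 to 0.279, so none passed. At a threshold of 0.1, 5 regions were higher in WD. These were the 4 mitochondrial regions and a nuclear one, all left out by this rule. A region in the body of Tet2, which encodes an enzyme that oxidises 5-methylcytosine (chromosome 3, 133518877 to 133519129), held 1.33 ± 0.424 CPM in CD and 7.70 ± 0.929 in WD (SD, n = 2). These rest on 9 and 23 counts, a WD over CD ratio of 5.20 (95% interval 2.32 to 12.8). A gene-end region overlapping Pla2g4a, which encodes cytosolic phospholipase A2 (chromosome 1, 149960871 to 149961830), held 29.5 ± 5.33 CPM in CD and 53.9 ± 6.50 in WD. Lrriq3, at 61.4 ± 5.30 and 107.2 ± 41.4 CPM, Rprm, at 18.2 ± 4.58 and 38.6 ± 17.6 CPM, and BC052040, at 38.3 ± 9.02 and 68.7 ± 21.0 CPM, also lay at gene ends. The log2 fold change at Lrriq3 was 0.74 with all libraries, 0.32 without WD replicate 1 and 1.143 without WD replicate 2, where it passed (edgeR adjusted p = 0.0194). At Rprm and BC052040 the log2 fold changes were 0.93 and 0.74 with all libraries. Without WD replicate 1 these were 0.45 and 0.43, and without WD replicate 2 they were 1.43 and 1.08. Klrb1b had 3 counts in CD and 14 in WD (ratio 9.50, 2.65 to 51.6). The remaining regions lay in the body of Prkn and 243825, 915487 and 7407 bases from Ndst4, Tbc1d32 and Prss39, the closest genes, with log2 fold changes of 1.74, 1.93, 1.44 and 0.80.

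At the 6 genes named for their roles in this system, the region nearest the gene end did not pass the test. Nlrp3, the inflammasome sensor in the title of the series, held 13.5 ± 0.935 CPM in CD and 15.3 ± 1.89 in WD (SD, n = 2), with a log2 fold change of 0.18 (95% interval -0.43 to 0.80). Il1b, which encodes interleukin-1 beta, stood at 24.4 ± 1.02 and 29.6 ± 3.72 CPM, with a log2 fold change of 0.29 (-0.19 to 0.77). Irf8, a transcription factor of the monocyte lineage, stood at 15.7 ± 2.50 and 23.8 ± 1.72 CPM (log2 fold change 0.63, SE 0.28, edgeR adjusted p = 0.54). Csf1r, the receptor for macrophage colony-stimulating factor, stood at 18.4 ± 3.52 and 14.8 ± 3.91 CPM (log2 fold change -0.30, -0.88 to 0.29). The granule protein genes Elane, at 21.4 ± 6.88 and 17.2 ± 3.37 CPM, and Mpo, at 76.0 ± 5.42 and 75.9 ± 19.3 CPM, had log2 fold changes of -0.19 and 0.05. At Mpo the sign of the fitted value goes against that of the means. The sign of both turned in at least 1 alternative.

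Regions at gene ends were higher in WD as a class, relative to the other regions. The classes together make up all regions, and each was tested against the rest. Lower values in gene bodies are therefore the other side of this result and not a separate one. The 12386 regions within 1000 bases of either end of a protein-coding gene had a median log2 fold change of 0.14, and 70.4% of them were higher in WD (camera adjusted p = 1.81e-09, and adjusted p = 0.0308 with an estimated correlation). They took 46.0% ± 0.32 of all counts in the CD libraries and 49.9% ± 0.64 in the WD libraries (SD, n = 2). This share includes the called mitochondrial regions. All mitochondrial regions together took 0.975% and 0.46% of counts in CD replicates 1 and 2, and 1.66% and 0.887% in WD replicates 1 and 2. Without them the gene-end median was 0.137 (camera adjusted p = 2.01e-09). The mean log2 CPM of gene-end regions, relative to all regions, was 1.001 and 1.049 in CD and 1.17 and 1.18 in WD. The 21717 regions in gene bodies had a median of -0.06 (camera adjusted p = 0.0131, and adjusted p = 0.0822 with an estimated correlation). The 18921 intergenic regions also had a median of -0.06 (camera adjusted p = 0.052). Wide regions stood higher than narrow ones: the medians of 4 width classes of about equal size, with median widths of 283, 401, 560 and 910 bases, were -0.195, -0.065, -0.0049 and 0.134. Quantile normalization ended the gene-end call (median 0.04, adjusted p = 0.252), and loess offsets on mean abundance lowered the median to 0.05 (adjusted p = 0.0149). Library-total scaling, which moved the median of all regions to -0.07, gave 0.06 at gene ends and -0.14 in both other classes.

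**Figure D2:**
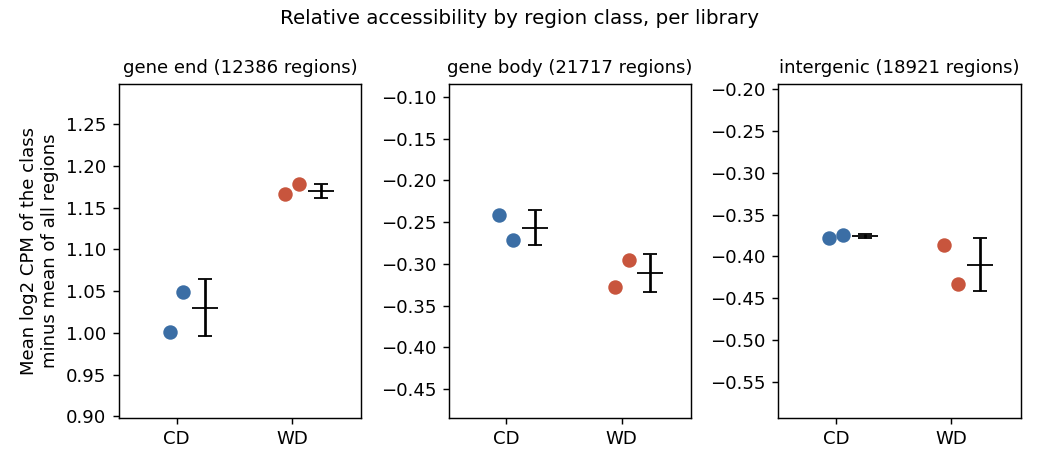
Mean log2 CPM of the regions at gene ends, in gene bodies and between genes, minus the mean of all regions, for each of the 4 libraries (points), with the mean and SD of the 2 libraries of each diet. At gene ends both WD libraries, at 1.17 and 1.18, lie above both CD libraries, at 1.001 and 1.049; the 3 panels span equal ranges.

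Regions of granulocyte genes were lower in WD as a set, and this was the only one of 17 gene lists to pass. The list joins granule protein, neutrophil receptor and granulocyte transcription factor genes, and had 86 regions assigned to 29 genes. Of these regions, 54 were lower and 32 higher in WD, with a median log2 fold change of -0.10 (camera adjusted p = 0.00799, and adjusted p = 0.722 with an estimated correlation). No region passed over all regions, and 1 was lower when adjusted over the list alone. For this and the other lists, the region given for a gene is the one of its regions with the largest moderated t. One of 3 regions of Retnlg, a resistin-like gene of neutrophils, held 6.16 ± 1.48 CPM in CD and 0.754 ± 1.07 in WD (SD, n = 2), the latter from 3 counts. One of 2 regions of Camp, the cathelicidin gene, held 38.7 ± 12.3 and 24.4 ± 8.86 CPM, and a region 129905 bases from Csf3r, the receptor for granulocyte colony-stimulating factor, held 8.24 ± 1.45 and 3.58 ± 1.504 CPM. The mean of the list relative to all regions was 0.49 and 0.26 in CD and -0.01 and 0.31 in WD, so the groups overlapped. Relative to the median of all regions, the list's median was 0.03 without CD replicate 1 (adjusted p = 0.442) and -0.04 without WD replicate 1 (adjusted p = 0.711).

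The toll-like receptor, cytokine receptor and inflammasome lists, unlike the interferon response list below, had negative medians without passing. The toll-like receptor and NF-kB list (271 regions) had a median log2 fold change of -0.12, with 162 regions lower, and the cytokine and growth factor receptor list (216 regions) of -0.13, with 131 lower (camera adjusted p = 0.185 for each). The inflammasome and IL-1 list (134 regions) had a median of -0.09, with 77 lower (adjusted p = 0.218). A region 81018 bases from Tlr4 held 1.82 ± 0.389 CPM in CD and 7.83 ± 4.68 in WD (SD, n = 2), whereas one 25241 bases from Tlr2 held 12.3 ± 0.676 and 5.55 ± 0.027, and one 43073 bases from Map3k8, a kinase downstream of these receptors, 24.0 ± 6.04 and 11.2 ± 2.68. The Tlr4 value in CD rests on 3 and 9 counts. When gene-end regions alone were compared with all gene-end regions, these lists and the granulocyte list were lower relative to that background (camera adjusted p of 0.00926, 0.0494, 0.0494 and 3.05e-07 in the order toll-like receptor, cytokine receptor, inflammasome, granulocyte). With an estimated correlation, the adjusted p was 0.494 for each of these 4 lists. Their own gene-end medians between the diets were -0.02, 0.0059, -0.00027 and -0.03 in that order, against 0.14 for all gene ends. The granulocyte list had an estimated correlation of 0.322 between its gene-end regions, against camera's preset of 0.01. Its median relative to gene ends was -0.17, and -0.08 without CD replicate 1, -0.37 without CD replicate 2, -0.14 without WD replicate 1 and -0.465 without WD replicate 2.

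The interferon response list had a median of 0.07, with 100 of its 174 regions higher (camera adjusted p = 0.417). Of its regions, 41.4% were gene ends, the class that was higher in WD, against 23.4% of all regions. Its gene-end regions had a median of -0.056 relative to all gene ends (camera adjusted p = 0.582). No region passed over all regions or adjusted over the list alone. One 1018 bases from Usp18, an interferon-induced protease gene, held 15.7 ± 7.69 CPM in CD and 28.5 ± 0.435 in WD (SD, n = 2), and one 27375 bases from Irf1 held 19.8 ± 3.31 and 10.4 ± 0.247. The AP-1 and immediate early list had a median of -0.04 (adjusted p = 0.642), and a region 30295 bases from Egr2 held 53.1 ± 8.63 and 31.1 ± 5.86 CPM. For other cell types of the marrow, medians were -0.06 for monocyte and macrophage genes (adjusted p = 0.51), -0.05 for stem and multipotent progenitor genes (0.619), 0.03 for megakaryocyte and erythroid genes (0.743), 0.01 for lymphoid genes (0.766), -0.06 for eosinophil, basophil and mast cell genes (0.185) and -0.04 for dendritic cell and MHC class II genes (0.766), with camera. When adjusted over the list alone, 3 monocyte and macrophage regions and 1 eosinophil, basophil and mast cell region were lower in WD. Regions 6668 bases from Zeb2, a transcription factor gene, and 5450 bases from Lyz1, a lysozyme gene, held 20.05 ± 3.68 against 8.24 ± 1.15 CPM and 10.2 ± 4.53 against 2.65 ± 0.191 CPM. A region in Hdc, the histidine decarboxylase gene of mast cells and basophils, held 15.6 ± 3.36 and 5.38 ± 2.35 CPM.

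Cholesterol and lipid handling genes had a median of 0.02, with 90 regions higher and 83 lower (camera adjusted p = 0.743). One region was lower when adjusted over the list alone. A region in the body of Abca1, the cholesterol efflux transporter, held 9.87 ± 2.78 CPM in CD and 1.97 ± 1.48 in WD (SD, n = 2). Its WD libraries held 1 and 6 counts, and its edgeR adjusted p over all regions was 0.249. Regions 37889 bases from Mylip, which encodes a ligase that targets the LDL receptor, and in Npc1, which exports cholesterol from lysosomes, held 6.28 ± 1.31 against 1.43 ± 0.602 CPM and 7.77 ± 1.52 against 3.33 ± 1.86 CPM. The WD libraries held 2 and 2 counts at Mylip, and 5 and 4 at Npc1. The glycolysis, HIF-1 and mTOR list had a median of -0.09 (camera adjusted p = 0.218), with 27.6 ± 7.502 and 12.1 ± 9.22 CPM in the body of Pfkfb3, a regulator of glycolysis. Medians were 0.03 for cell cycle genes (0.619), 0.06 for chromatin enzymes (0.619) and 0.05 for housekeeping genes (0.619). When adjusted over the list alone, 1 chromatin enzyme region was higher and 1 lower in WD. Housekeeping regions at gene ends, overlapping Rplp0 and Eef1a1, held 53.9 ± 2.72 against 79.7 ± 5.38 CPM and 102.7 ± 5.46 against 135.9 ± 0.833 CPM. In the megakaryocyte, lymphoid, cholesterol, cell cycle, chromatin enzyme and housekeeping lists the median was positive and the mean negative, and camera pointed down for the cholesterol list and up for the other 5. No list passed with an estimated correlation or with fry. In 4 of the 17 lists both WD libraries lay on 1 side of both CD libraries, where 5.67 are expected by chance.

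**Figure D3:**
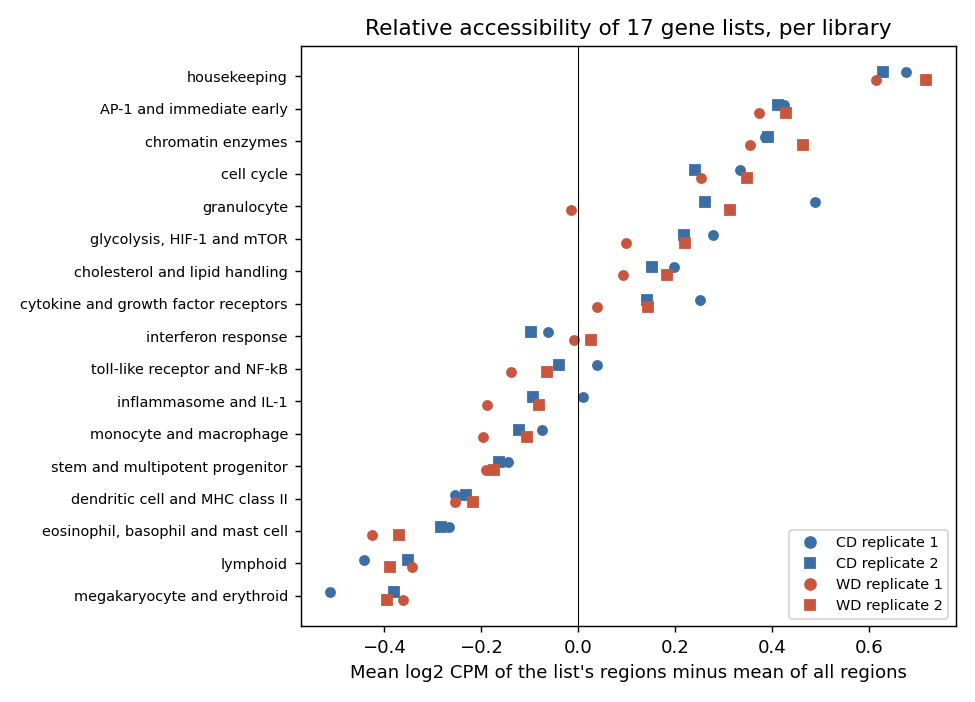
Mean log2 CPM of the regions of each of 17 gene lists minus the mean of all regions, for each of the 4 libraries (blue, CD; red, WD; circles, replicate 1; squares, replicate 2). In the granulocyte list WD replicate 1, at -0.01, lies lowest, and WD replicate 2, at 0.31, lies between the CD libraries at 0.26 and 0.49.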

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

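Alternatives chosen after the data were seen were RLE and library-total scaling, removal of the mitochondrial regions, limma, thinning, the test per gene, loess offsets for regions and lists, lists by the nearest gene end, and, for region classes, all but quantile normalization and loess. The 5 regions past the threshold stayed 5 with RLE size factors and became 7 with library totals, which include the same 5. The number was 1 with the least accessible regions filtered out, 1 without the mitochondrial regions, 9 at a threshold of 0.1, and 0 with quantile normalization, loess offsets, limma with each of the pseudocounts 0.5, 1 and 5, thinning, DESeq2 and the test per gene. Unadjusted p under 0.05 then covered 4038, 3715, 4907, 4984, 5194, 4050 and 651 regions and 884 of 15061 genes. With 1 library left out it ran from 0 to 4: 4 without CD replicate 1, 0 without CD replicate 2, 1 without WD replicate 1 and 4 without WD replicate 2. The calls without CD replicate 1 and without WD replicate 2 were all higher in WD, and included the 2 mitochondrial regions called above. With all libraries 2 were higher and 3 lower. The calls at Adk and Mark3 were lost with any 1 library left out, and that at Epg5 with any but WD replicate 1, while the 3 fold changes stayed negative. Library totals moved the median of all regions to -0.07 and the share of higher regions from 50.1% to 42.1%, so lists are given relative to all regions. Each such fit assumes that the lone library varies like the others.

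The gene-end shift ended its call with quantile normalization (0.0374), kept it with library totals (0.0624) and loess offsets (0.0472), and ran from 0.120 to 0.165 with 1 library left out. The gene-body shift lost its call with quantile normalization (-0.0360), loess offsets (-0.0421), an estimated correlation (-0.0622) and without CD replicate 1, and kept it with library totals (-0.138), over a range of -0.112 to -0.0495 with 1 library left out. The intergenic shift passed with the filter on low regions (-0.0635), RLE (-0.0487) and without WD replicate 1, over a range of -0.0977 to -0.0474. Quantile normalization equalises the distributions of the libraries, and the cause of the other changes was not tested.

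The 1 list past the threshold became 0 with limma at a pseudocount of 0.5, an estimated correlation and fry, 4 with gene-end regions alone, and 0 to 1 with 1 library left out. The granulocyte list's median relative to all regions was -0.103. It was -0.187 with limma at 0.5 (adjusted p = 0.0592), and kept its call at -0.279 after thinning (0.0164), -0.201 with quantile normalization (0.00918), -0.185 with limma at 1 (0.0408) and, relative to gene ends, -0.172 at gene ends (3.05e-07; -0.465 to -0.0753 with 1 library left out). An estimated correlation (adjusted p = 0.722) leaves the median at -0.103, as does fry (0.557), which tests the list against no change and not against other regions. With 1 library left out it ran from -0.291 to 0.0319, the latter without CD replicate 1. Over the alternatives run on all 4 libraries its adjusted p ran from 3.05e-07 to 0.722.

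None of the lists that changed sign below passed in the main test or in that alternative. With the filter, the megakaryocyte list stood at -0.00405, the lymphoid list at -0.000289 and the cholesterol list at -0.000584. With quantile normalization, cholesterol stood at -0.0121, cell cycle at -0.00517 and housekeeping at -0.0334. With loess offsets, dendritic cell stood at 0.00724 and cholesterol at -0.0132. Cell cycle stood at -0.00403, -0.00593 and -0.00555 with limma at 0.5, 1 and 5. After thinning, eosinophil stood at 0.0353, dendritic cell at 0.00222 and cholesterol at -0.00445. At gene ends, interferon stood at -0.0560, lymphoid at -0.0324 and cholesterol at -0.0868. With 1 library left out, the ranges were -0.0266 to 0.133 (megakaryocyte), -0.0356 to 0.114 (lymphoid), -0.0825 to 0.0484 (cholesterol), -0.0240 to 0.112 (cell cycle), -0.0115 to 0.125 (housekeeping), 0.00108 to 0.0147 (dendritic cell), -0.0598 to 0.0127 (AP-1) and -0.0400 to 0.0978 (chromatin enzymes). The region of Elane ran from -0.566 to 0.0989 and that of Mpo from -0.265 to 0.245. Mpo stood at -0.206 with quantile normalization, -0.0231 with library totals, -0.143 with loess offsets and -0.0234, -0.0231 and -0.0209 with limma at 0.5, 1 and 5. The cause was not tested.

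In counts simulated for these 4 libraries, 24.2% of 2-fold changes were called, and 43.5% among regions with counts above the median; the parts of depth, number of libraries and spread were not separated. Not run were all alternatives for WD>CD, the motif families, limma without trend, and TMM and the 4-library fit, which became the main choices.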

Other observations

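The test of region width and abundance was set before its result was seen, and the other tests below, like the gene families, were chosen after the result was seen. Among 12 families of genes defined by their symbols, and compared with all gene-end regions, chemokines and their receptors (24 regions) had a median log2 fold change of -0.13 and interleukins and their receptors (43 regions) of -0.02, and both were lower in WD relative to gene ends (camera adjusted p = 0.0147 each). Zinc finger protein genes of the Zfp series were higher, with a median of 0.22 and 262 of 316 regions up (adjusted p = 0.0377). With an estimated correlation the adjusted p was 0.512, 0.541 and 0.512. Genes of the chemokine and interleukin families also stand in the toll-like receptor, inflammasome and cytokine receptor lists. These families are therefore no separate support for the lower values of those lists relative to gene ends. Cytosolic ribosomal protein genes had a median of 0.20, with 61 of 73 regions higher, and did not pass (adjusted p = 0.134).

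Gene-end regions were higher and other regions lower in WD, a difference of medians of 0.20. The difference was at least 0.203 in each of 10 draws thinned to equal totals. Thinning keeps the same regions and leaves the expected ratios between libraries as they were. It therefore bears on counting noise alone, and a part of library depth in how the regions were chosen or filtered stays open. Within cells of width and abundance it was 0.092, positive in 58 of 70 cells, between the bound of 0.05 set for these properties as the cause and that of 0.1 against them, so they may account for part of it. Signal-to-noise and GC bias cannot be told apart from diet. The gene-end share of counts, which includes mitochondrial regions, was 3.94 percentage points higher in WD. Neither GC content nor reads outside regions were used here. The 2 other ways to pair the 4 libraries gave gene-end medians of 0.02 and 0.0066 and 0 calls each; 3 splits are too few for a share under 0.05. An effect of diet stays open.

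Relative to library size, all 4 mitochondrial regions had log2 fold changes of 0.89 to 0.95, and 2 of them passed. A ceiling on their counts from removal of duplicate reads is a candidate explanation. The largest ratio between libraries of a mitochondrial region's count was 1.09, against 3.67 for the library totals, and no such region exceeded 1.82 counts per base. More mitochondrial DNA per cell in WD was not tested.

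The granulocyte list was lower in WD with camera's preset correlation, and did not pass with an estimated one (adjusted p = 0.722), and its library levels overlapped. WD replicate 1 alone may give this: over all its regions the level in WD replicate 2 minus the CD mean was -0.0629, and it lay above CD replicate 2. At gene ends, however, it stood at -0.18, below the CD libraries at 0.26 and -0.09, so that explanation stays open, and the list also changed sign without CD replicate 1 (0.0319). Fewer cells at later granulocyte stages in the sort would lower late genes most. Late genes (19) had a median of -0.32 and early genes (8) of -0.11, a difference of 0.202 (permutation p = 0.218), which decides neither way. An effect of diet on these genes stays open.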
